A study of Caenorhabditis elegans with 2 samples.

How the data were processed

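Chromatin immunoprecipitation and sequencing with an antibody against green fluorescent protein was performed on whole hermaphrodites of C. elegans strain OP463, which expresses tagged NHR-102, at the L4 stage, 50 h after synchronization. Per the labels, chromatin was sheared with a microtip sonicator and 2 biological replicates were made. The label of the antibody names nhr-102, while the description of the samples names an antibody against the tag, and the latter is used here. Both samples form 1 group, and their replicate numbers were taken from the labels, so that no comparison between conditions was possible.

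The deposited files used here were peak lists, in the genome builds ce10 and ce11. Per the notes the submitters deposited with each sample, the same control file was used for both replicates, and an optimal list of reproducible peaks was derived from both replicate lists and the pooled list with the irreproducible discovery rate (IDR). Each replicate list and the pooled list held exactly 30000 peaks, and the optimal list 2796 in ce11 and 2795 in ce10. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The signal of each peak is the authors' own value from their caller, and it was used only to rank and describe peaks within a list. The deposited -log10 q of each peak ranged from 0.244 to 2.91 in the pooled list and stood at a single ceiling value in every row of the optimal list, so it was not used as a filter. A stricter threshold was therefore set by signal. Among the 2796 optimal peaks, 79 shared their interval with another peak and differed in summit, so summits were used throughout. The lists give no read numbers, so the depth behind each peak is unknown. Exact binomial (Clopper-Pearson) 95% intervals on shares of peaks or genes cover counting error only.

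Positions are given from 1 in ce11. The reference was the assembly WBcel235, which is the same sequence as ce11, with the gene annotation of Ensembl release 115. The last ce11 peak of each chromosome ended within the reference chromosome. Lists in ce10 were compared only with each other. Mitochondrial protein-coding genes, unnamed in the gene annotation, were given RefSeq symbols by position. A promoter window ran from 1000 bp upstream to 200 bp downstream of each annotated 5' end of a protein-coding transcript, and a summit in several windows counted for each gene. In C. elegans many 5' ends of mature transcripts are made by trans-splicing, so an annotated 5' end can lie downstream of the start of transcription.

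Replicates were compared by the share of optimal peaks whose summit lay in one of the N strongest peaks of each replicate list, with N the number of optimal peaks, and by Spearman's rho across matched peaks with 1000 bootstrap resamples. The promoter share was tested against 10000 random placements of as many summits on the same chromosomes, one-sided. For 24 gene lists, members with a promoter summit were compared with the other protein-coding genes by Fisher's exact test, two-sided. For 11 motifs and all 7-mers, presence on either strand within 50 bp of the summit was compared with presence in a window of the same size centred 300 bp to a random side by an exact McNemar test. P-values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05. One member of the intestine list, opt-2, matched no gene name. The gene lists, the motifs, the tests, the alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to have been made after seeing the data. The rule took the genes whose promoter held the 25 strongest peaks or, outside promoters, the nearest 5' end, up to 4 members of each gene list with the highest signal at a promoter summit or up to 6 for a list past the threshold, nhr-102 and unc-119 whatever their values, and up to 6 peaks whose rank differed most between replicates. ZK1193.2, named among the tRNA summits, was chosen after its values were seen.

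The tests were checked on simulated data. With random gene sets, 1 of 50 runs over the 24 lists gave a call, and 150 of 150 planted lists were called. The planted lists were those of ribosomal proteins, cytochrome P450 genes and histones, with 72 to 78 members, so short lists were not checked. Members were planted on top of those drawn at random. The planted shares exceeded those found here in all but the ribosomal and propionate lists, so sensitivity to smaller shares was not checked. Genes were drawn singly, so windows shared by neighbours were not simulated. No motif and none of 8192 7-mers was called between opposite flanks of the same peaks, and a motif and a 7-mer planted in 5% of peaks were both called. These checks did not include the difference in GC content between summits and flanks. The promoter test called 1 of 20 runs without an effect and 20 of 20 with 10% of summits moved to a 5' end. Calculations were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures with matplotlib 3.10.9. Alternatives covered the genome build, the overlap rule, the number of replicate peaks, narrower and wider promoter and motif windows, other backgrounds, the strongest peaks alone and each replicate alone. Alternatives without mitochondrial peaks and with other control sequences were chosen after seeing the data. Signal tracks, alignments and any strain without the tag were not analysed here.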

Results

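Binding of NHR-102, a nuclear hormone receptor of Caenorhabditis elegans, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole hermaphrodites of strain OP463. These animals carry an integrated transgene with NHR-102 fused to green fluorescent protein and a wild-type copy of unc-119 that marks it, and the fusion protein was precipitated with an antibody against the fluorescent tag. L4 larvae were collected 50 h after synchronization by L1 starvation. The series held 1 group with 2 biological replicates, so the comparisons were between the replicates, between peak summits and random positions, and between sets of genes or sequences within 1 peak list. The final list of reproducible peaks, called here the IDR list after the irreproducible discovery rate used to make it, held 2796 peaks in build ce11. The read depth of the libraries is unknown from these peak lists, and every peak signal is the authors' own value, comparable only within a list.

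Peaks of the NHR-102 precipitation were found on every chromosome, and the strongest lay on the mitochondrial genome and on X. Mitochondrial peaks stood at 1667 per Mb, against 24.0 to 32.8 per Mb on the nuclear chromosomes. No strain without the tag was analysed here. Binding by NHR-102 therefore cannot be told apart from other sources of signal at these peaks. The 2796 peaks had a median width of 444 bp and covered 1042 kb, 1.04% of the genome. Of the 25 peaks of highest signal, 10 lay on the mitochondrial genome, 12 on X, and 1 each on III, IV and V. The highest signal of all, 4514, stood in ND5 of the mitochondrial genome (positions 11602 to 12897), a subunit of respiratory complex I, followed by a peak in CYTB, the cytochrome b gene (4134 to 5755; signal 3778), and one whose summit lay upstream of the 5' end of ND4 (5906 to 6364; signal 3398). Further mitochondrial peaks among the 25 had summits in the promoter windows of COX1, COX2, ATP6, CYTB, ND1, ND2, ND3 and ND5, windows that overlap neighbouring genes on this compact genome.

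Away from the mitochondrial genome, the strongest peaks of X were mostly distant from protein-coding 5' ends. Only 1 of the 12 X peaks among the 25 strongest had its summit in a promoter window, 1000 bp upstream to 200 bp downstream of an annotated 5' end. That peak stood at -710 bp from the 5' end of nspc-17, negative values being upstream (X, 14525425 to 14526374; signal 2006). The strongest X peak (11093760 to 11094555; signal 2297) was intergenic, and its nearest 5' end was that of W02H3.3. The next (6296168 to 6296966; signal 2054) lay in an intron, with cest-16 as the nearest 5' end. For the other 9 the nearest 5' ends were those of K02D3.1, ZK899.6, T27A8.7, gtr-1, C41A3.2, F55G7.5, F20B6.9, F22H10.2 and xol-1, the master switch of sex determination, with signals between 1583 and 1778. The X peak nearest to C41A3.2 had its summit in a coding exon, and those nearest to the remaining 8 genes were intergenic. The sequence CGCGCAGG lay within 100 bp of the summit in the peaks nearest to W02H3.3, cest-16, T27A8.7, gtr-1, F20B6.9, F22H10.2 and xol-1. The 3 autosomal peaks of this group were in promoters: rpl-3, a protein of the large ribosomal subunit (III, 3867250 to 3867839; signal 1849), the histone gene his-37 (V, 9546766 to 9547470; signal 1677), and the window shared by rpl-20 and Y17G9B.5 (IV, 4749830 to 4750314; signal 1556).

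**Figure D1:**
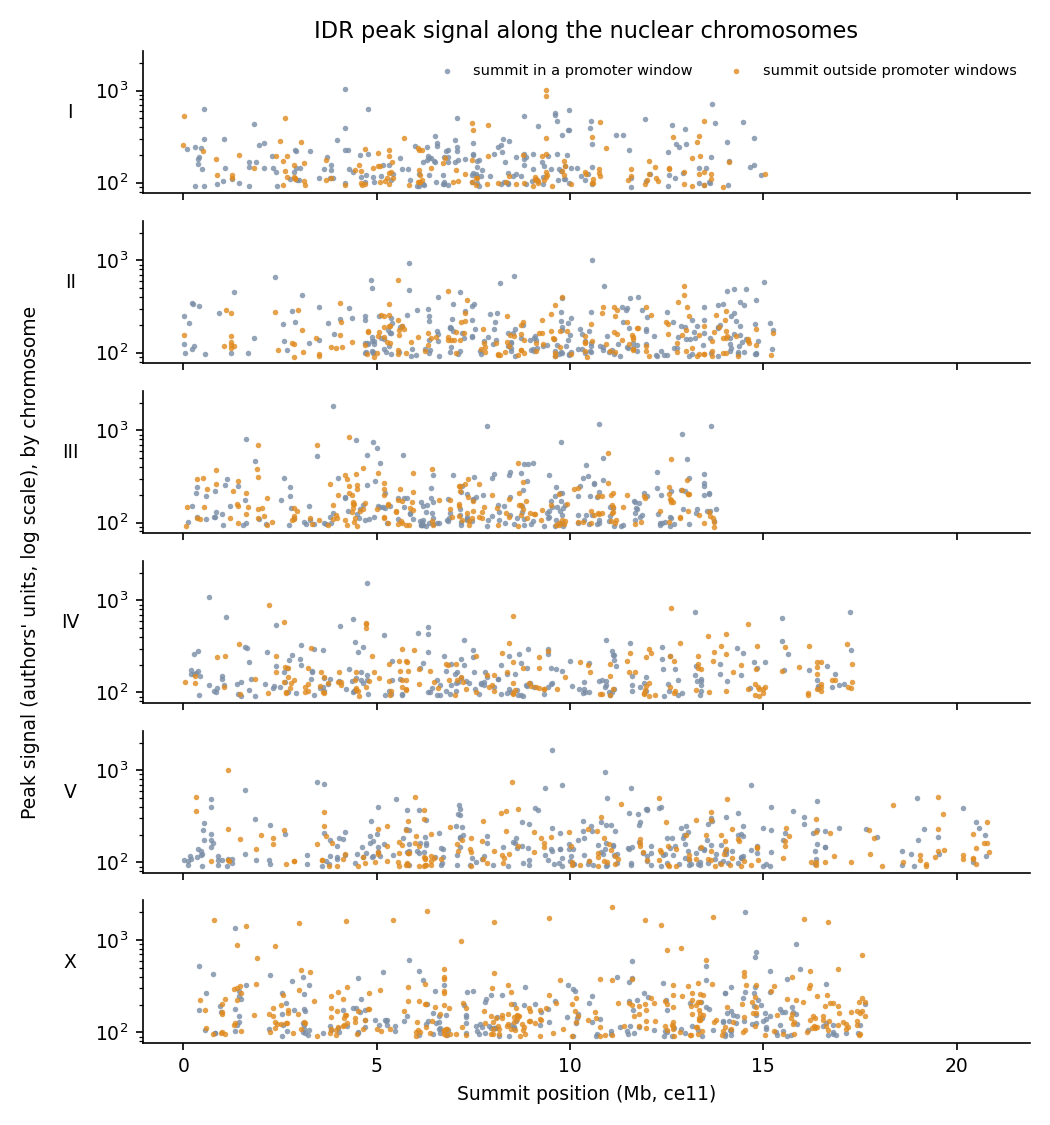
Signal of each nuclear IDR peak (log scale, in the authors' units) against the position of its summit in Mb, with 1 panel per chromosome and the colour showing whether the summit lay in a promoter window. X holds 12 of the 25 strongest peaks of the list, 1 of them in a promoter window. Among the 200 strongest nuclear peaks, 36 of 56 on X and 42 of 144 on the autosomes lie outside promoter windows.

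Across chromosomes, 361 peaks lay on I, 448 on II, 450 on III, 425 on IV, 508 on V, 581 on X and 23 on the mitochondrial genome. Peak density was highest among nuclear chromosomes on X (32.8 per Mb) and III (32.7 per Mb) and lowest on I (24.0 per Mb). Promoter windows held 42.5% of X summits (247 of 581, exact 95% interval 38.5 to 46.7%) and 54.7% to 59.8% of the summits of each autosome. X also had less of its length in promoter windows, 21.8% against 24.3% to 30.1% of the autosomes. Relative to this coverage, the promoter share was 1.95 times random on X and 1.99 to 2.38 times on the autosomes.

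The first comparison asked whether the replicates found the same sites. The strongest peaks were shared by both: the ND5, CYTB and ND4 peaks held ranks 1, 2 and 3 in each replicate's own list, and rpl-3 ranked 12 and 10. Of the 2796 IDR peaks, 1875 (67.1%, exact 95% interval 65.3 to 68.8%) had their summit in one of the 2796 strongest peaks of both replicates, against a mean of 30.7 peaks (1.10%) for 10000 random placements on the same chromosomes. Another 827 peaks were among the strongest of exactly 1 replicate and 94 of neither. In the full lists of 30000 peaks per replicate, 2737 IDR peaks (97.9%) were found in both. Spearman's rho between the 2 replicates' signals across these 2737 peaks was 0.674, with a bootstrap 95% interval of 0.650 to 0.700. By these measures agreement was higher in the strong peaks. Of the 1398 weakest IDR peaks, 543 (38.8%) were among the strongest of both, and rho was -0.266 over 1369 matched peaks. The values for the 1398 strongest were 95.3% and 0.704. These sets were cut by pooled signal, which rises with the signals of both replicates (1849 at rpl-3, against 925 and 927). Within the narrow pooled range of the weaker set, a peak higher in 1 replicate tends to be lower in the other. Its peaks also lie near the limit of the 2796 strongest. The cut alone can thus give a negative rho and a lower share, so neither value shows that the replicates disagree at weak peaks. The IDR list was itself derived from both replicates, and peaks are not independent replicates, so no p-value is given.

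The median ratio between a peak's ranks in the 2 lists was 1.47, and it exceeded 10 for 35 of the 2737 matched peaks. The peak with the largest difference lay 1905 bp downstream of the 5' end of sec-61.A, the alpha subunit of the protein translocation channel of the endoplasmic reticulum (IV, 14822228 to 14822569), and ranked 21432 in replicate 1 and 560 in replicate 2. The promoter of lsm-3, a splicing and decay factor, ranked 26779 and 948 in the same order. The opposite order was seen at C17G10.10 (ranks 529 and 18659), at mrpl-55, a mitochondrial ribosomal protein (871 and 20057), and at peaks outside promoters nearest to F13D11.3 (838 and 21343) and C16C8.17 (1104 and 27731). The strongest IDR peak absent from a replicate's list was the COX1 peak of the mitochondrial genome (6902 to 7173), which no peak of replicate 1 covered at its summit and which ranked 8 in replicate 2.

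**Figure D2:**
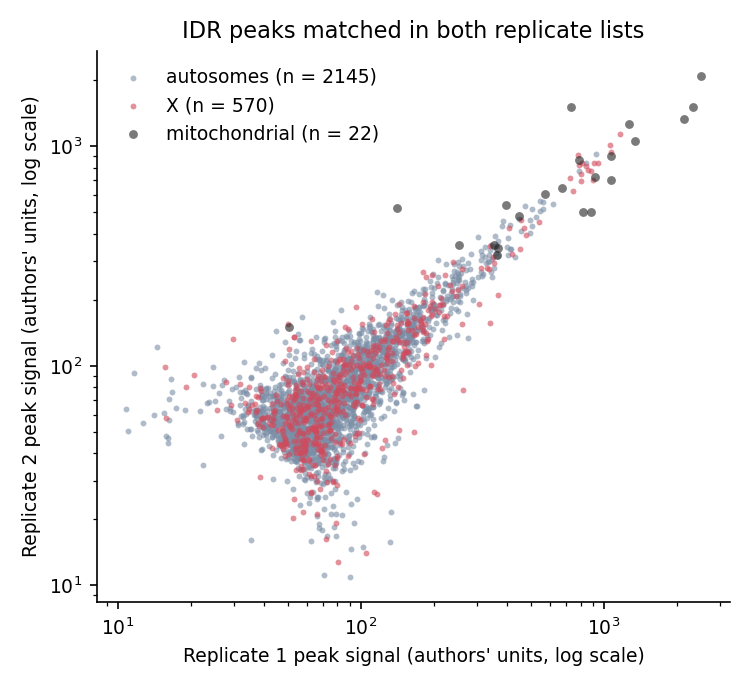
Peak signal in replicate 1 (horizontal) and replicate 2 (vertical), both on log scales in the authors' units, for the 2737 IDR peaks matched in both lists. Points are single peaks coloured by autosomes, X or mitochondrial genome, with mitochondrial peaks at the highest signals (Spearman's rho 0.674 over all of them).

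The second comparison asked where the summits lay relative to genes. Promoter windows held 1526 of the 2796 summits (54.6%, exact 95% interval 52.7 to 56.4%), 2.07 times the mean of 736 (SD 23.1) given by random placement on the same chromosomes. The one-sided permutation p was 0.0001, the smallest that 10000 placements can give. Summits in promoters lay mostly just upstream of the gene: 1295 of the 1526 were upstream of the nearest 5' end, and the median position of promoter summits was -184 bp. The 200 bp directly upstream of a 5' end held 20.9% of all summits against 4.73% of random positions. Of the 1270 summits outside promoter windows, 635 (50.0%) were intergenic, 357 (28.1%) in introns and 121 (9.53%) in coding exons, where random positions outside the windows gave 33.5%, 37.0% and 25.3%. Genes for small RNAs (tRNA, snRNA, snoRNA, miRNA or rRNA) held 95 of these summits (7.48%), against 0.0967% of random positions. On the mitochondrial genome, where promoter windows covered 77.1% of the length, the promoter share of 82.6% (19 of 23) did not exceed random placement (permutation p = 0.37).

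**Figure D3:**
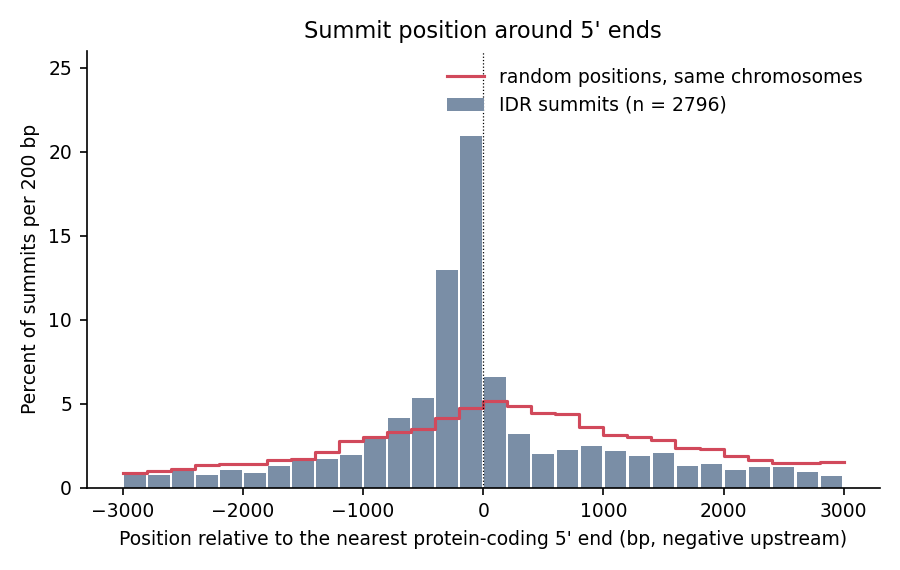
Percent of summits per 200 bp against their position relative to the nearest protein-coding 5' end (bp, negative upstream), with bars for the IDR summits and a line for random positions on the same chromosomes. The bin directly upstream of the 5' end reaches 20.9% against 4.73% at random.

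The third comparison asked which genes had a promoter summit. Of 19985 protein-coding genes, 1789 (8.95%) had one, and 380 summits lay in the windows of 2 or more genes, for each of which they were counted. Of 24 gene lists fixed in advance, 9 held such genes more often than the remaining genes and 2 less often, while 13 did not pass the threshold (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p under 0.05).

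Ribosomal protein genes had the highest share of the 24 lists, with a promoter summit in 49 of 78 cases (62.8%, exact 95% interval 51.1 to 73.5%) against 8.74% of the other genes, an odds ratio of 17.6 (exact adjusted p = 9.08e-31). After rpl-3 and rpl-20, the strongest were rpl-35 (signal 1122), rpl-15 (1074), rps-1 (786) and rpl-12 (743). The nuclear genes of the mitochondrial respiratory chain had one in 20 of 58 cases (34.5%; odds ratio 5.40; exact adjusted p = 5.2e-07). They were led by the cytochrome c oxidase subunits cox-5A (signal 915), cox-6A (448) and cox-5B (331), with atp-1 of the ATP synthase (427), mev-1 of succinate dehydrogenase (306) and ucr-2.2 of complex III (274) beside them. Heat shock protein and chaperone genes followed with 14 of 51 (27.5%; odds ratio 3.87; exact adjusted p = 0.000523), among them hsp-60, the mitochondrial chaperonin (signal 814), the cytosolic chaperone hsp-90 (685), the co-chaperone dnj-9 (611), and hsp-3 of the endoplasmic reticulum (461). Histone genes had a summit in 17 of 72 cases (23.6%; odds ratio 3.16; exact adjusted p = 0.00065), but these 17 shared 13 peaks, as his-67 with his-68 (signal 370) and his-61 with his-62 (288). Set against random lists matched on the distance to the upstream neighbour, the histone list no longer passed (permutation adjusted p = 0.082). With each summit given to its nearest 5' end, neither the histones (exact adjusted p = 0.339) nor the heat shock list (exact adjusted p = 0.0896) passed.

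The list of propionate and vitamin B12 genes, which holds enzymes of the vitamin B12-dependent route and of the shunt without it as well as regulators, had the second highest share. Of its 14 members, 8 had a promoter summit (57.1%, exact 95% interval 28.9 to 82.3%; odds ratio 13.6; exact adjusted p = 4.47e-05, Fisher's exact test). The strongest was nhr-68, a nuclear hormone receptor that activates the shunt, with a signal of 648 at a summit -401 bp from its 5' end, in a window shared with H12C20.7 (V, 11572772 to 11573260, intergenic, replicate signals 347 and 308). It was followed by hach-1 (signal 187), acdh-1, the first enzyme of the shunt (173), hphd-1 (139), ech-6 (134) and pccb-1, a subunit of propionyl-CoA carboxylase (127). The wider list of fatty acid breakdown, which also contains acdh-1 and ech-6, had 13 of 73 (17.8%; odds ratio 2.21; exact adjusted p = 0.0317), led by acs-2, an acyl-CoA synthetase (signal 209.7), the carnitine palmitoyltransferase gene cpt-2 (195), and the lipase gene lipl-5 (140.2). Its call was lost without either replicate: with replicate 2 alone the odds ratio was 1.74 and the exact adjusted p 0.199, and with replicate 1 alone 1.49 and 0.368.

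Cytochrome P450, UDP-glucuronosyltransferase and nuclear hormone receptor genes also had a promoter summit more often than the other genes. Of the cytochrome P450 genes, 15 of 74 had one (20.3%; odds ratio 2.60; exact adjusted p = 0.00805), led by cyp-13A12 (signal 485), cyp-13A8 (388) and cyp-37B1 (206), while cyp-33C6 and cyp-33C7 shared a peak (255). UDP-glucuronosyltransferase genes, which conjugate small molecules, had 14 of 67 (20.9%; odds ratio 2.70; exact adjusted p = 0.00638), led by ugt-20 (signal 441), ugt-40 (424), ugt-37 (377) and ugt-41 (329.6). Nuclear hormone receptor genes had 36 of 274 (13.1%; odds ratio 1.55; exact adjusted p = 0.0408), led after nhr-68 by nhr-178 (signal 603), nhr-47 (482), nhr-35 (392), nhr-142 (367) and nhr-135 (337). The nhr-47 peak was shared with dnj-19, which counted in the heat shock list, and the nhr-142 peak with F44E7.9. The receptor list lost its call with replicate 2 alone (odds ratio 1.40; exact adjusted p = 0.169), with replicate 1 alone (1.35; exact adjusted p = 0.181), and with a window of 500 bp upstream to 100 bp downstream, where the odds ratio was 1.60 (exact adjusted p = 0.0546).

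Chemoreceptor and cuticle genes were bound less often than other genes. Of 1162 chemoreceptor genes, 14 had a promoter summit (1.21%, exact 95% interval 0.660 to 2.01%; odds ratio 0.117; exact adjusted p = 5.79e-30), the strongest being srh-2 (signal 400), srh-16 (389.6), srh-83, in a window shared with ugt-41 (329.6), and sri-5 (329). Cuticle collagen genes had 5 of 175 (2.86%; odds ratio 0.297; exact adjusted p = 0.00638), namely col-63 (signal 215), col-185 (187), col-38 in a window shared with rpl-5 (181), col-20 (133) and sqt-3 (91.0). With each summit given to its nearest 5' end, the collagen list turned to an odds ratio of 1.04 (exact adjusted p = 0.896), while in the window of 500 bp upstream to 100 bp downstream it was 0.0794 (exact adjusted p = 0.000443).

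The markers of intestine, germline, neurons, sperm, pharynx and body wall muscle did not pass the threshold in either direction. Intestine markers had a summit in 4 of 19 cases (exact adjusted p = 0.134): the brush border actin act-5 (signal 211), the intestinal GATA factor elt-2 (208), mtl-1 (98.3) and pept-1 (96.5). This list passed with replicate 1 alone (odds ratio 3.78; exact adjusted p = 0.0401), in the window of 2000 bp upstream (3.63; exact adjusted p = 0.0257) and with each summit given to its nearest 5' end (5.66; exact adjusted p = 0.00277). Germline and oocyte genes had 4 of 36 (exact adjusted p = 0.611), led by puf-9 (signal 607), with mex-1 (179), cgh-1 (177) and syp-4 (166). The gene puf-9 entered this list through its family name and was not chosen singly as a germline marker. Neuronal genes had 2 of 51 (unc-31, signal 136, and snb-1, 93.8; exact adjusted p = 0.406), sperm genes 2 of 74 (spe-48, signal 255, and spe-46, 142; exact adjusted p = 0.116), pharyngeal genes 1 of 31 (pha-4, signal 118; exact adjusted p = 0.605) and body wall muscle genes 0 of 21 (exact 95% upper limit 16.1%; exact adjusted p = 0.356). The unc-31 summit lay in a small RNA gene.

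Other metabolic and signalling lists also missed the threshold. Glutathione S-transferase genes had 8 of 47 (exact adjusted p = 0.116), led by gst-33 (signal 738), gst-7 (500.9), gst-44 (468) and gst-42 (226). This list passed with either replicate alone (exact adjusted p = 0.0328 with replicate 2 and 0.0391 with replicate 1), with the window of 500 bp upstream to 100 bp downstream (odds ratio 2.87, exact adjusted p = 0.0262), and among the 1398 strongest peaks (odds ratio 4.04, exact adjusted p = 0.00702). Vacuolar ATPase and lysosome genes had 8 of 43 (exact adjusted p = 0.105), among them vha-1 (signal 173), vha-8 (169.9), asp-12 (149) and hlh-30 (132). With replicate 1 alone this list passed (odds ratio 3.65, exact adjusted p = 0.00329). Fatty acid synthesis and desaturation had 4 of 24 (fat-4, signal 172, nhr-49, 153, elo-6, 135, and elo-1, 127; exact adjusted p = 0.244) and passed with replicate 2 alone (odds ratio 4.50, exact adjusted p = 0.00844). Methionine, SAM and phosphatidylcholine genes had 2 of 22 (ahcy-1, signal 191, and mthf-1, 133; odds ratio 1.02, exact adjusted p = 1), and with replicate 1 alone 5 of 22 (odds ratio 3.11, exact adjusted p = 0.0676). Of the vitellogenin and lipid transport genes, 1 of 24 had a summit (lbp-3, signal 329; exact adjusted p = 0.75). In a window of 2000 bp upstream, the methionine, vacuolar and fatty acid synthesis lists passed (exact adjusted p = 0.00471, 0.00177 and 0.00801), and they also passed with each summit given to its nearest 5' end. Innate immune effectors had 13 of 125 (exact adjusted p = 0.605), led by cpr-9 (signal 378), cpr-4 (209) and spp-3 (155), and insulin signalling genes 2 of 51, the insulin-like peptide gene ins-39 (signal 1363) and akt-2 (107), with an exact adjusted p of 0.406. The cpr-9 summit lay in a small RNA gene, in a window shared with gcy-33.

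The background and the strength of the peaks changed the number of calls. Among the 6849 genes with any pooled pre-threshold peak in the window, 4 of the 11 lists still passed: ribosomal proteins (odds ratio 6.76, exact adjusted p = 3.57e-13), histones, cytochrome P450 genes and cuticle collagens. In that background 14 of 54 chemoreceptor genes had an IDR summit (odds ratio 0.99, exact adjusted p = 1), and the propionate (odds ratio 3.78, exact adjusted p = 0.0648) and respiratory chain lists (2.03, exact adjusted p = 0.0795) also missed the threshold. So did glucuronosyltransferases, fatty acid breakdown, heat shock proteins and nuclear hormone receptors, with odds ratios of 2.09, 1.15, 1.53 and 1.51 (exact adjusted p = 0.154, 0.904, 0.499 and 0.166). Among the 1398 strongest peaks, ribosomal proteins, the respiratory chain, heat shock proteins, histones and chemoreceptors still passed, and the other 6 lists did not, among them the propionate list (3 of 14; odds ratio 5.35, exact adjusted p = 0.0836) and fatty acid breakdown, whose odds ratio turned to 0.839 (exact adjusted p = 1).

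**Figure D4:**
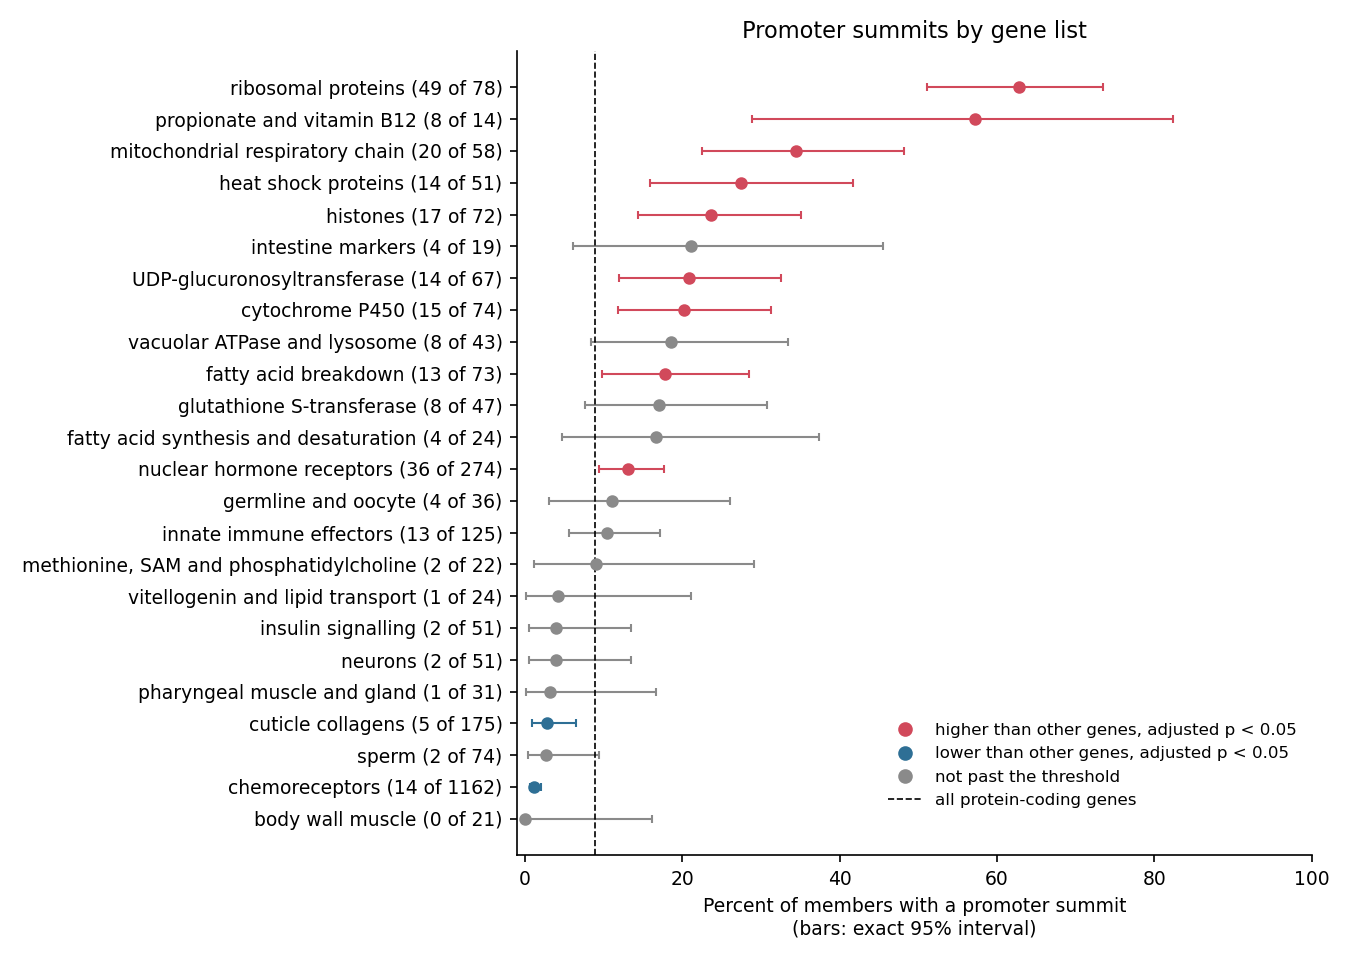
Percent of the members of each of the 24 gene lists with an IDR summit in the promoter window, with exact 95% intervals as bars and the share of all protein-coding genes (8.95%) as a dashed line. Ribosomal proteins (62.8%) and the propionate and vitamin B12 list (57.1%) lie farthest above the line, and chemoreceptors (1.21%) and cuticle collagens (2.86%) lie below it with their whole interval.

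No peak was found at the tagged gene itself. The nhr-102 gene (WBGene00003692; V, 15874093 to 15876408, minus strand) had no summit within 5 kb in the IDR list, the pooled list or either replicate's list of 30000 peaks. The nearest summit was 108 kb away in the pooled list and 37.0 kb away in replicate 1. At unc-119 (WBGene00006843; III, 10902641 to 10908935, plus strand), the neuronal gene whose copy marks the transgene, no IDR summit lay within 5 kb. The interval without a pooled summit around nhr-102 ran for 260.4 kb and held the 5' ends of 34 chemoreceptor genes. Near unc-119 the pooled list had 2 summits, the stronger ranking 17122 (signal 27.9).

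The fourth comparison asked which DNA sequences stood at the summits more often than in the flanks of the same peaks. An E-box (CACGTG) lay within 50 bp of the summit in 6.83% of peaks against 1.61% of flanks, a GA repeat (GAGAGAGA) in 4.61% against 0.966%, and the GATA site TGATAA, recognised by intestinal GATA factors, in 16.9% against 10.1%. The adjusted p-values were 3.35e-22, 6.7e-17 and 7.23e-13 (exact McNemar test over 2796 pairs, 11 motifs). With replicate 2 alone the E-box stood at 5.72% against 2.07%, a ratio of 2.76 in place of 4.24, and with flanks centred 500 bp away the ratio of the GA repeat was 8.06 in place of 4.78. The TATA element TATAAA was less frequent at summits, 7.51% against 12.2% (exact adjusted p = 1.05e-08). Half-sites of nuclear hormone receptors did not pass the threshold in these windows. AGGTCA was present in 2.97% of summits and 2.40% of flanks (exact adjusted p = 0.254), AAGTCA in 3.72% and 4.58% (0.168), the HNF4-type core CAAAGTCC in 0.429% and 0.322% (0.664), and the DAF-12-type half-site AGTGCA in 4.51% and 3.65% (0.168). AP-1, CRE-type and forkhead sites did not pass either (exact adjusted p = 0.656, 0.117 and 0.137). Within 100 bp of the summit, AGGTCA passed narrowly (ratio 1.28; exact adjusted p = 0.0493), as did AGTGCA (ratio 1.39; exact adjusted p = 0.000938) and the CRE-type and forkhead sites (exact adjusted p = 0.00992 for each). AGTGCA also passed with replicate 2 alone (ratio 1.36; exact adjusted p = 0.0336), with replicate 1 alone (exact adjusted p = 0.00347) and with flanks centred 500 bp away (ratio 1.57; exact adjusted p = 0.00344). With replicate 2 alone the CRE-type and forkhead sites passed too (exact adjusted p = 0.0249 and 0.0336).

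Among all 8192 7-mers, 1007 were more frequent at summits and 632 less frequent (adjusted p under 0.05). The 10 with the smallest p among the more frequent ones were CTGCGTC, GAGACGC, ACGCAGA, AGACGCA, CTCTCTC, AGAGACG, CTGGCGC, AACGCGC, GCCAGCA and GAGAGAC. Several of them overlap, so the 10 are not separate signals. In the order GAGAGAC, AGAGACG, GAGACGC, AGACGCA, GACGCAG (the reverse complement of CTGCGTC) and ACGCAGA, each continues the one before it. Likewise GCGCCAG, the reverse complement of CTGGCGC, overlaps GCCAGCA. Overlapping 7-mers were counted singly in all the counts given here. CTGCGTC stood at 7.76% of summits against 1.04% of flanks (exact adjusted p = 6.22e-34), CTCTCTC at 8.58% against 1.93%, and GCCAGCA at 3.61% against 0.215%. GCCAGCA was found in 6 flanks only, and its ratio of 16.8 was 6.77 with replicate 2 alone, where 13 flanks held it, as with replicate 1 alone. The ratio of AACGCGC was 11.1, and it was 4.62 with replicate 2 alone and 5.60 with replicate 1 alone. Summit windows had a GC content of 44.0% and flanks 35.7%. Against the same summit sequences shuffled with their dinucleotides kept, a control chosen after seeing the data, 613 7-mers passed. These held 280 of the 1639 in the same direction, the 10 named ones among them, and 294 others that had not passed against flanks. The rest were members of the 1639 whose direction turned. Against this control the ratios of AACGCGC, CTGGCGC and GCCAGCA were 1.97, 3.18 and 5.05, in place of 11.1, 10.3 and 16.8. That of CTGCGTC was 7.23 in place of 7.48, and among the 10 only GAGACGC had a higher ratio, 7.68 in place of 7.17. The TATA element then turned from rarer to more frequent (7.51% against 5.29%; exact adjusted p = 0.000898), while the E-box, the GA repeat and the GATA site stayed more frequent, at 2.77, 2.63 and 2.91 times the control. Against this control AAGTCA was less frequent at summits (ratio 0.65; exact adjusted p = 0.000898) and the CRE-type site more frequent (ratio 6.5; exact adjusted p = 0.000164). Promoters lacking a summit, taken at the same distance for 1507 peaks, were another control chosen after seeing the data. There the ratios were 3.68 for the E-box, 6.00 for the GA repeat and 0.554 for the TATA element. The GATA site stood at 14.5% against 10.9% (ratio 1.33; exact adjusted p = 0.0101). AAGTCA was again less frequent (ratio 0.663; exact adjusted p = 0.0344), while the CRE-type site did not pass (exact adjusted p = 0.198).

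**Figure D5:**
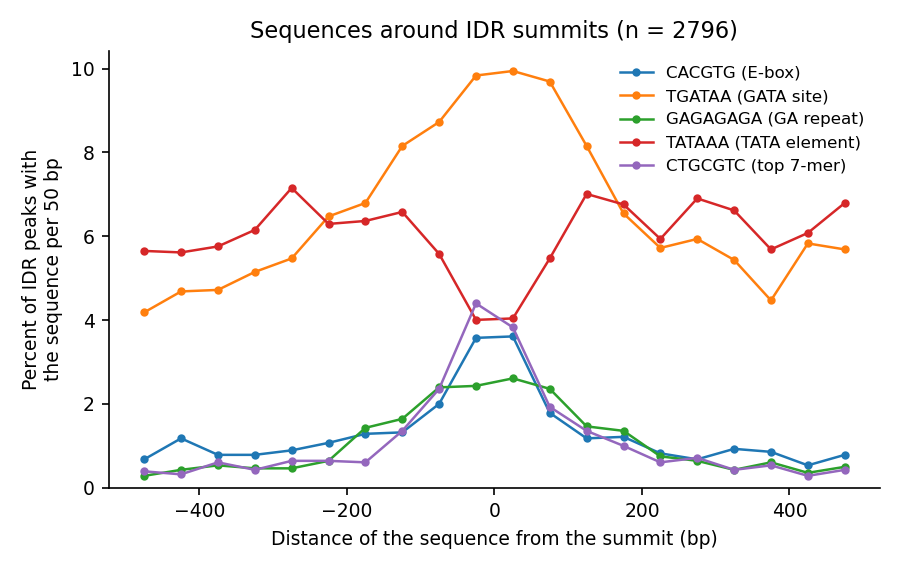
Percent of the 2796 IDR peaks with each sequence per 50 bp against its distance from the summit in bp, with 1 line per sequence. CACGTG, TGATAA, GAGAGAGA and CTGCGTC rise towards the summit, CACGTG to 3.61% of peaks in the 50 bp to its right, and TATAAA falls to 4.01% in the 50 bp to its left.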

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

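The alternatives without mitochondrial peaks, with shuffled sequences and with promoters lacking a summit were chosen after seeing the data; the others were planned. The promoter share stayed above random placement in all 6 alternatives. Taking the 1398 strongest peaks, fewer by construction, gave 971 genes with a promoter summit, 6 gene lists past the threshold (5 of the 11 and 1 gained) and 889 7-mers (818 of the 1639 and 71 gained), raised the share of peaks among the strongest calls of both replicates to 95.3% and gave a rho of 0.704. That share was 50.5% with reciprocal overlap of 50%, 64.4% with summits within 100 bp, 92.5% with double the number of strongest peaks per replicate and 97.9% in their full lists, and rho was 0.704 with summits within 100 bp. Among the 1398 weakest IDR peaks, under the main rule, the share was 38.8% and rho -0.266, values that the cut by pooled signal itself shapes. A background of genes with a pooled peak kept 4 of the 11 gene lists past the threshold and gained 0, and 13136 fewer genes entered that test. Windows of 100 bp to each side gave 8 motifs past the threshold and windows of 51 bp 757 7-mers (715 of the 1639 and 42 gained). Shuffled sequences gave 613 7-mers (280 of the 1639 in the same direction, 294 gained and the rest of the 1639 with the direction turned). Promoters lacking a summit gave 1086 (850 of the 1639 and 236 gained), over 1507 peaks. With 1 replicate alone, 5 to 7 motifs and 11 to 12 gene lists passed, 9 of the 11 reported lists among them each time. Where a list or motif passed the threshold in at least 1 of the 2 settings compared, direction turned in 3 cases: the odds ratio of fatty acid breakdown was 0.839 in the strongest peaks (exact adjusted p = 1), that of cuticle collagens 1.04 with summits given to the nearest 5' end (exact adjusted p = 0.896), and the TATA element was 1.42 times as frequent as in shuffled sequences. For single lists, 20 other comparisons lost a call, 15 gained one and 179 kept their call or their lack of one; for single motifs, 12 gained a call and 86 kept theirs or their lack of one. Items without a call in both settings turned direction in some of these, among them insulin signalling, with an odds ratio of 1.29 in place of 0.414 when summits were given to the nearest 5' end. The cause of these changes was not tested. Fewer peaks or genes entered some alternatives by construction. In the background of genes with a pooled peak the odds ratios moved as well, so the smaller number of genes need not account for the lost calls. Depth is unknown, so its effect on these counts could not be measured.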

Other observations

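The test of the chemoreceptor intervals, the comparison of X with the autosomes and the counts at small RNA genes were chosen after the results were seen; the remaining tests were set before their values were known.

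Genes for small RNAs carried many summits. Of 612 nuclear tRNA genes, 248 (40.5%, exact 95% interval 36.6 to 44.5%) had a summit within 200 bp, against a mean of 8.50 (SD 3.07) for random placement, 29.2 times as many. The counts were 39 of 129 snRNA genes (22.5 times random) and 82 of 346 snoRNA genes (16.3 times random), each with a permutation p of 0.0001, the smallest that 10000 placements can give (0.00014 adjusted over 7 sets). For miRNA genes it was 13 of 261, 3.52 times random (adjusted permutation p = 0.00117), and for nuclear rRNA genes 0 of 20, where random placement gave 0.408. Among X peaks outside promoters and outside the 200 strongest nuclear peaks, 84 of 298 lay within 200 bp of a tRNA gene, against 80 of 890 such autosomal peaks. These shares were not adjusted for how many tRNA genes each chromosome carries, so they do not show a preference of X peaks for such genes. The strongest tRNA summit lay in an intron on X (409995 to 410535; signal 530.4), in the promoter window of ZK1193.2.

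Summits at tRNA genes were weighed first. Reads that fall on several identical gene copies are a candidate explanation, and 17.4% of the 224 summits (39, exact 95% interval 12.7 to 23.0%) had a central 50 bp found more than once in the genome, against 0.863% of other nuclear summits. That share lies between the bounds set for and against this explanation, so it remains open. The position of tRNA genes inside protein-coding promoters is argued against, since 166 of the 419 tRNA genes more than 200 bp from every promoter window also had a summit, against a mean of 5.86 at random (permutation p = 0.0001, the smallest that 10000 placements can give). No biological explanation was tested for these summits.

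Strong peaks on X away from promoters were weighed next. Among the 200 strongest nuclear peaks, 36 of 56 X peaks lay outside promoters against 42 of 144 autosomal peaks (odds ratio 4.37; Fisher's exact p = 9.2e-06). Copies of a repeat are argued against, since 0 of the 36 had a repeated central 50 bp (upper 95% limit 9.74%). CGCGCAGG, the core of the element that recruits the dosage compensation complex to X, lay within 100 bp of the summit in 10 of the 36 and in 1 flank (exact McNemar p = 0.0117), and in 0 of the 42 autosomal peaks. A candidate explanation for these 10, among them the peaks nearest to W02H3.3, cest-16, gtr-1 and xol-1, is that they coincide with such recruitment sites, while the other 26 lacked the sequence.

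The absence of a peak at nhr-102 was weighed last. The interval without a summit around the gene was 260.4 kb long in the pooled list (V, 15766401 to 16026763), 260.5 kb in replicate 2 and 146.1 kb in replicate 1, and at least 99.87% of the intervals holding a protein-coding 5' end were shorter in each list. The bound set for extra transgene copies of the locus raising the control was thus passed, but this length cannot decide it. Pooled intervals with 5 or more chemoreceptor genes had a median of 75.5 kb, also above the pooled bound of 55.3 kb. At unc-119, also on the transgene, 2 pooled summits, 3 in replicate 1 and 1 in replicate 2 lay within 5 kb. The strongest in each list had signals of 27.9, 20.2 and 10.4, near or below the list medians of 30.8, 19.1 and 18.5. These weak summits do not decide it either. The pooled interval held the 5' ends of 90 genes, 34 of them chemoreceptors (50 and 17 in replicate 1), and a silent chemoreceptor cluster may give the same gap: 95.89% of the 73 pooled intervals with 5 or more chemoreceptor genes were shorter, between the bounds set for and against it, with 87.8% in replicate 1 and 97.3% in replicate 2. Both explanations stay open, and control coverage was not analysed here.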
